A study of Homo sapiens with 9 samples.

How the data were processed

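RNA was measured in 9 libraries of AC16 cells, 3 per group, and each library was assigned to low glucose, high glucose or high glucose with chrysin from its treatment label. The labels describe polyA RNA and a commercial messenger RNA library kit. The submitters' processing notes name fastp 0.23.4, HISAT2 2.2.1, StringTie 2.2.1, HTSeq 0.13.5 and the genome build hg38, with no roles. Which tool made the deposited table, the annotation release and whether counting used strand are not given in the sources used here. The deposited table held FPKM (fragments per kilobase of transcript, scaled to library size) for 60671 genes in 9 columns, a unit read from the values because no header names it. The libraries' FPKM sums ran from 690850 to 704369. Of the rows, 1094 carried a repeated gene name and were tested as separate genes. In every library the low values were whole multiples of a step per gene, which gave whole reads, up to a common divisor, for all 28230 genes above 0 in 2 or more libraries, with every value within 4.6e-05 reads of a whole number. Values shifted at random by up to about 10% matched at no more reads for 33 of these genes (0.117%), at a tolerance of 0.002 to 0.08 reads. The 4119 genes above 0 in 1 library match by construction and were given 1 read. The other 28322 genes were at 0 in every library. Recovered reads totalled 18171842 to 23024300 per library and were 99.92% of the total implied by genes with a single transcript.

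The main test was limma 3.58.1 in R 4.3.3 with a mean-variance trend, on log2(FPKM + 0.5), over genes with a mean of at least 0.5 FPKM in at least 1 group. All 9 libraries entered 1 fit with a mean per group and no block, and each of the 3 comparisons was a two-sided contrast. Genes with a Benjamini-Hochberg adjusted p under 0.05 among the 16996 tested were called. This was the branch fixed for normalized values; the branch fixed for deposited counts was not used. Exact permutation of 3 against 3 libraries cannot go below a p of 0.1 for a single gene. Genes changed back were those called in both high glucose comparisons with opposite sign, set against 100 simulations of unchanged groups sharing the high glucose libraries and against independent lists of the same sizes.

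The 36 gene lists, the tests, the naming rule and most alternatives were fixed before the data were examined. The lists covered ferroptosis drivers and suppressors, iron, glutathione and NRF2, fatty acid synthesis and oxidation, cholesterol, lipid droplets, glycolysis, glucose sensing through MondoA, oxidative phosphorylation, mitochondrially encoded genes, ATF4, ER stress, heat shock, the aryl hydrocarbon receptor, p53, cell cycle, hypoxia, NF-kB, interferon, extracellular matrix, TGF-beta and YAP, immediate early genes, apoptosis, autophagy, metallothioneins, markers of 6 cell types, ribosomal proteins and replication histones. Lists share some genes: HSPA5, for example, is in the ER stress list and among the ferroptosis suppressors. Each list was tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over the lists within a comparison. Members were counted at an adjusted p under 0.05 over all genes and over the list alone.

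Named genes were the 8 largest rises and 8 largest falls among called genes with a mean log2 of at least 1, a symbol and groups that did not overlap. SCD, ACSL4, GPX4, SLC7A11, TFRC, FTH1, HMOX1, CYP1A1, CYP1B1, TXNIP and ARRDC4 were named whatever their value, as were up to 4 members per list with the smallest p, 8 genes changed back with the smallest larger p of the pair, and called members of the cell type lists. Some list members are not reported here by name. A symbol was taken as a unique name that is not a clone-based one. Positions, biotypes, GC content and length came from GENCODE 29 on hg38, in which 56539 genes were matched. GC content and length were known for 16710 of the 16996 genes tested (98.3%).

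The alternatives were pseudocounts of 0.1 and 1, no filter, a mean of at least 5 FPKM, median-of-ratios scaling, limma voom on recovered reads, the replicate number as a block, a fit of only the groups compared, a minimum absolute log2 fold change of 1, and leaving out each library in turn. After the data were seen, a loess correction of each library for GC content and length (span 0.4), leaving out mitochondrially encoded genes, and counting list members without single libraries were added.

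The test was tried on simulated data with 200 genes changed, 50 at each size, besides a gene list shifted together. For high against low glucose (16864 simulated genes) it called 18%, 70%, 80% and 96% of genes changed by 0.25, 0.5, 1 and 2 on the log2 scale. For chrysin against high glucose (16821 genes) it called 30%, 66%, 80% and 96%. False calls made up 10.6% and 6.37% of the calls, above the nominal share in both, with 17 and 10 unchanged genes called. Each simulation was a single draw with few genes changed, so neither the shares called nor the false shares carry over to the data. Reads were recovered for 100% of simulated genes. Tables and figures were made with python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.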

Results

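Polyadenylated RNA was sequenced in 9 libraries of AC16 cells, a human line made by fusing ventricular heart cells with fibroblasts. The labels place 3 libraries in each of 3 groups: cells given low glucose, cells given high glucose, and cells given high glucose together with chrysin, a plant flavonoid. Glucose concentrations, the chrysin dose and the length of treatment are not given in the sources used here. The series title concerns diabetic cardiomyopathy, ferroptosis (cell death driven by iron and lipid peroxidation) and SCD1, the protein of the gene SCD. Values were FPKM for 60671 genes, of which 32349 were above 0 in at least 1 library. Reads recovered from these values came to 20863778, 18171842 and 19063949 in the low glucose libraries 1 to 3, to 20331424, 23024300 and 19457798 in high glucose, and to 18329839, 18670835 and 22158982 with chrysin. On a principal component plot the first axis (45.4% of the variance) separated the chrysin libraries from the other 6, and the next (14.9%) separated low from high glucose. Mitochondrially encoded genes took 2.79% to 3.04% of the reads in the low and high glucose libraries and 3.80% to 3.89% with chrysin. At genes with over 10000 reads in a pair of libraries together, high glucose library 1 stood apart from libraries 2 and 3 of its group (chi-square per gene 28.1 and 31.5, against 4.82 to 7.44 in the other replicate pairs). Fold changes are on the log2(FPKM + 0.5) scale, which understates the change of low genes, and adjusted p-values are from limma. The labels do not say whether replicates were separate cultures, so these p-values measure only the spread between these libraries, which may be technical.

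SCD is the gene of the series title. It encodes stearoyl-CoA desaturase, which makes monounsaturated fatty acids (chromosome 10, 100347124 to 100364834, plus strand, hg38). Its mean was 157 ± 5.4 FPKM in low glucose, 149 ± 5.5 in high glucose and 174 ± 3.2 with chrysin (SD, n = 3). With chrysin SCD was 1.16-fold higher than in high glucose alone (log2 fold change 0.22, SE 0.04, adjusted p = 0.00051). It was higher than in low glucose by 0.15 (adjusted p = 0.005), a call that was lost with median-of-ratios scaling (0.09, adjusted p = 0.058). The difference between high and low glucose did not pass the test (-0.07, SE 0.04, adjusted p = 0.19), but passed it with limma voom on recovered reads (-0.10, adjusted p = 0.018).

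SLC7A11, the cystine importer that feeds glutathione synthesis, moved more than SCD, ACSL4, GPX4, TFRC, FTH1 or HMOX1 in both comparisons with high glucose. It fell from 17.5 ± 0.32 FPKM in low glucose to 12.1 ± 1.2 in high glucose and rose to 25.9 ± 1.1 with chrysin (SD, n = 3). The log2 fold changes were -0.51 (SE 0.07, adjusted p = 0.00042) and 1.07 (SE 0.07, adjusted p = 8.1e-07). GPX4, the peroxidase that reduces lipid hydroperoxides, fell with chrysin from 135 ± 8.1 to 103 ± 6.2 FPKM (-0.39, adjusted p = 0.00013) and did not pass the test in high glucose (0.05, adjusted p = 0.5). ACSL4, which activates polyunsaturated fatty acids for use in phospholipids, rose with chrysin from 86.5 ± 6.7 to 112 ± 2.6 FPKM (0.37, adjusted p = 0.00013). ACSL4 was lower in high than in low glucose by a small margin (-0.17, adjusted p = 0.033). That call was lost without low glucose library 1, 2 or 3 (adjusted p = 0.063, 0.068 and 0.11) and without high glucose library 1 (-0.10, 0.057) or 2 (0.06), and with no filter (0.089) or only the groups compared (0.09). TFRC, the transferrin receptor, rose with high glucose (0.20, adjusted p = 0.0037) and again with chrysin (0.41, adjusted p = 1.1e-05). FTH1, the ferritin heavy chain, fell with chrysin (-0.15, adjusted p = 0.0026, or -0.22 after the GC and length correction). FTH1 did not pass in high glucose (-0.06, adjusted p = 0.19), though it did without high glucose library 1 (-0.09, 0.011) and with limma voom (-0.09, 0.013). FTH1 overlaps BEST1 on the other strand, and whether counting used strand is not given in the sources used here.

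HMOX1, the heme oxygenase that releases iron from heme, rose with chrysin from 20.9 ± 1.7 to 30.2 ± 2.2 FPKM (SD, n = 3; log2 0.52, adjusted p = 0.00013). HMOX1 in high against low glucose stood at 0.22 (adjusted p = 0.042), but the call depended on which libraries entered. It was lost without low glucose library 1, 2 or 3 (adjusted p = 0.13, 0.051 and 0.098), without high glucose library 2 or 3 (0.14 and 0.098), without chrysin library 3 (0.057), and with median-of-ratios scaling (0.072), limma voom (0.082), no filter (0.098), only the groups compared (0.067) or correction for GC content and length (0.13). CYP1B1, an enzyme induced by the aryl hydrocarbon receptor, rose in high glucose (0.28, adjusted p = 0.002) and fell with chrysin from 95.7 ± 5.1 to 24.1 ± 1.1 FPKM (-1.96, adjusted p = 1.7e-09). CYP1A1, another such enzyme, stayed below 1 FPKM in the mean of every group and passed in neither comparison (0.26, adjusted p = 0.37, and -0.31, adjusted p = 0.21).

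**Figure D1:**
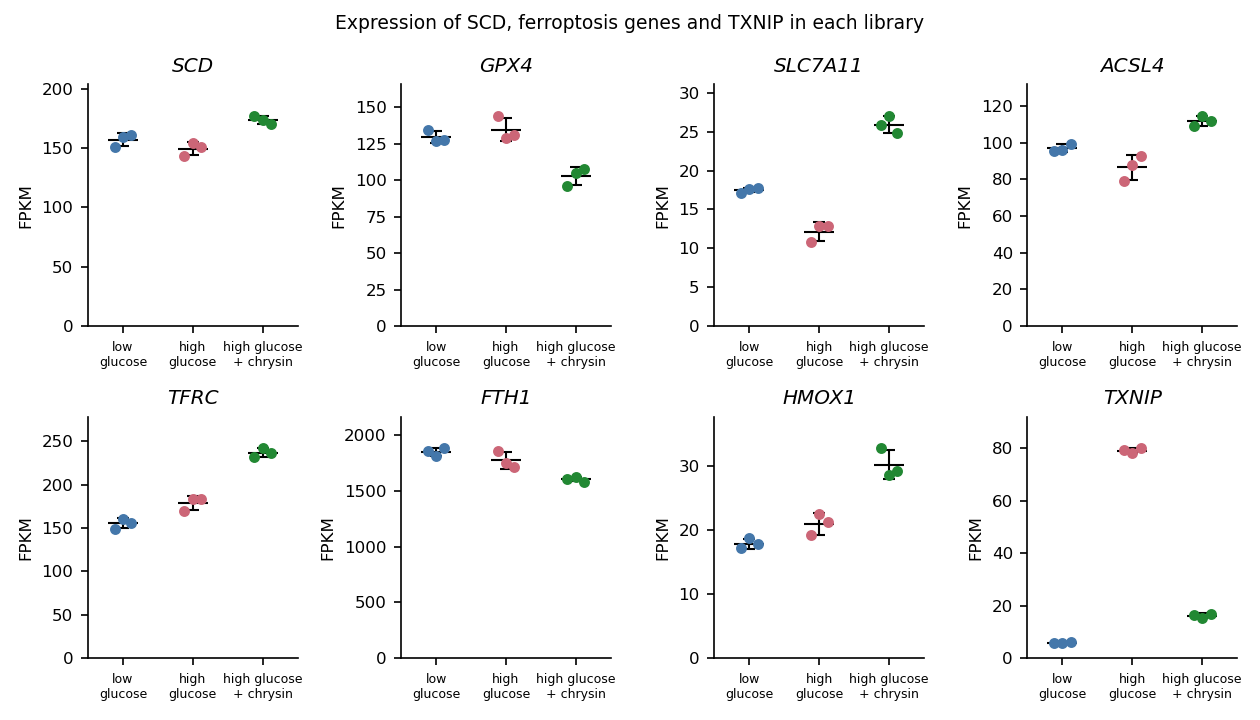
FPKM of 8 genes in each of the 9 libraries; points are libraries, horizontal bars are group means and error bars are the SD (n = 3). SCD lies at a mean of 157 in low glucose, 149 in high glucose and 174 with chrysin, and TXNIP at 5.9, 79.2 and 16.3.

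High glucose against low glucose asked what the sugar level changed in these cells. TXNIP, an inhibitor of thioredoxin and of glucose uptake (chromosome 1, 145992435 to 145996600, minus strand), rose 12.4-fold, from 5.9 ± 0.17 to 79.2 ± 0.91 FPKM (SD, n = 3; log2 3.64, SE 0.05, adjusted p = 8.8e-12). Genes of endoplasmic reticulum (ER) stress were much lower in high glucose. DDIT3, the stress-induced transcription factor CHOP (chromosome 12, 57516588 to 57521737, minus strand), fell 10.2-fold, from 103 ± 5.2 to 9.67 ± 0.075 FPKM (log2 -3.35, SE 0.07, adjusted p = 2.4e-10). HSPA5, the main ER chaperone (BiP), fell from 1240 ± 48 to 279 ± 4.5 FPKM (-2.14, SE 0.03, adjusted p = 8.8e-12). DDIT3 overlaps MARS and MBD6 on the other strand.

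The other largest falls were mostly of the same kind: HERPUD1 (-2.63) and DERL3 (-2.39) of ER-associated degradation, the ER co-chaperones DNAJB9 (-1.98) and SDF2L1 (-1.75), and TRIB3 (-1.81), a pseudokinase induced by DDIT3 and ATF4. MIR616 (-2.85) lies within DDIT3 on the same strand, so its reads cannot be told from those of DDIT3. The other largest rises were MIR210HG (1.40), the host transcript of a hypoxia-induced microRNA, STC1 (1.24), a secreted glycoprotein, PFKFB4 (1.11), a regulator of glycolysis, the aldo-keto reductase AKR1C3 (1.13), which has near-identical paralogs, and the adaptor DOK3 (1.10). The mitochondrial transfer RNAs MT-TW (1.78) and MT-TF (1.34) rested on few reads (1 to 13 per library for MT-TW), and MT-TF lost its call with limma voom (1.39, adjusted p = 0.1). ARRDC4, a relative of TXNIP, rose from 0.369 ± 0.083 to 1.07 ± 0.12 FPKM (0.86, SE 0.17, adjusted p = 0.0047), by 1.33 with a pseudocount of 0.1, and by more with limma voom (adjusted p = 2.5e-05).

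Of the 36 gene lists, 4 were called in high against low glucose both with camera's preset correlation and with an estimated correlation. In the ER unfolded protein list 24 of 27 genes fell (24 when adjusted over the list alone), with a median of -0.85 (camera adjusted p = 1.6e-35, and 0.0016 with an estimated correlation). MANF (-1.23), a secreted ER stress protein, was among them. Of the list 1 gene rose, and none did without low glucose library 2 or 3 or high glucose library 1 or 2. In the integrated stress list, targets of the transcription factor ATF4, 29 of 35 fell (30 adjusted over the list alone), with a median of -0.55 (5.4e-32, estimated 0.0016). Examples were PPP1R15A (-1.01), which restores translation after stress, and AARS1 (-0.78), a transfer RNA synthetase. Heat shock genes rose in 11 of 20 cases (12 over the list alone, median 0.14, 8.4e-05, estimated 0.03), among them DNAJA1 (0.53), HSPA1B (0.50) and BAG3 (0.47). G2/M genes rose in 19 of 32 cases (23 over the list alone, median 0.16, 1.8e-09, estimated 0.017), among them the mitotic kinase AURKA (0.44), the kinesin KIF20A (0.47) and MKI67 (0.38). Members outside the naming rule were chosen after their values were seen.

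In 10 more lists the call in high against low glucose was lost with an estimated correlation, whose adjusted p stands last in each bracket. Glycolysis genes rose in 14 of 25 cases and fell in 2, SLC2A3 (-0.24) and HK2 (-0.36); the counts were 14 and 2 adjusted over the list alone (adjusted p = 0.00015, and adjusted p = 0.2 with an estimated correlation). LDHA (0.32) and the lactate exporter SLC16A3 (0.40) were among those that rose. Glucose-sensing MondoA targets rose in 10 of 20 cases and fell in 3 (12 and 3 over the list alone; adjusted p = 0.008, and adjusted p = 0.12 with an estimated correlation), with OGA (0.67) and KLF10 (0.62) beside TXNIP. Genes induced by hypoxia rose in 14 of 29 cases and fell in 5 (14 and 5 over the list alone; adjusted p = 0.019, and adjusted p = 0.21 with an estimated correlation). JMJD6 (0.58) was among those that rose, and VEGFA (-0.56) and DDIT4 (-0.65) among those that fell. Mitochondrially encoded genes rose in 8 of 13 cases (9 over the list alone; adjusted p = 8.4e-05, and adjusted p = 0.21 with an estimated correlation), among them MT-ND2 (0.39) and MT-CO3 (0.42), and none fell except 1 without low glucose library 2. Replication histones rose in 5 of 18 cases (5 over the list alone; adjusted p = 0.0028, and adjusted p = 0.077 with an estimated correlation). These 5 were H2AC6 (0.95), H2BC11 (0.88), H3C10 (0.66), H2BC5 (0.62) and H1-2 (0.60), of which H3C10 lost its call with no filter (0.057).

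S phase genes rose in 16 of 40 cases and fell in 4 in high against low glucose (18 and 5 over the list alone; adjusted p = 0.019, and adjusted p = 0.13 with an estimated correlation). That call was also lost with median-of-ratios scaling (0.066), limma voom (0.077) and the GC and length correction (0.079). With a mean of at least 5 FPKM the calls of S phase (0.075), hypoxia (0.075) and MondoA (0.052) genes were lost. Targets of TGF-beta and YAP fell in 14 of 29 cases and rose in 3 (15 and 3 over the list alone; adjusted p = 6e-05, and adjusted p = 0.055 with an estimated correlation), with the matricellular protein CCN1 (-0.64) and tissue factor F3 (-0.62) among those that fell. Cholesterol synthesis genes fell in 8 of 27 cases and rose in 2, with 9 and 2 over the list alone (adjusted p = 0.0056, and adjusted p = 0.21 with an estimated correlation). Only 5 fell without low glucose library 3, and 1 rose without low glucose library 1 or high glucose library 2 or 3. Suppressors of ferroptosis fell in 9 of 32 cases and rose in 4 (9 and 4 over the list alone; adjusted p = 0.02, and adjusted p = 0.12 with an estimated correlation). HSPA5 and SLC3A2 (-0.72), the partner of SLC7A11, fell, and GCLM (0.23), of glutathione synthesis, rose. The suppressors were not called without high glucose library 3 (0.052), and 5 fell without low glucose library 2. Ribosomal protein genes fell in 21 of 76 cases (25 over the list alone, median -0.09; adjusted p = 2.5e-10, and adjusted p = 0.43 with an estimated correlation). The number that fell was 52 without high glucose library 1, 9 without low glucose library 1, 9 without high glucose library 2 and 11 without high glucose library 3.

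The remaining 22 lists were not called in high against low glucose (camera adjusted p from 0.059 to 0.98), and the members that passed the test are given as counts, with those adjusted over the list alone in brackets. Drivers of ferroptosis rose in 8 of 26 cases (10) and fell in 4 (5), with LPCAT3 (0.24), of phospholipid remodelling, and CHAC1 (-1.28), which degrades glutathione, on opposite sides. Only 5 rose without low glucose library 1 or 3 or high glucose library 3, and 2 fell without high glucose library 2. Glutathione and NRF2 targets rose in 11 of 30 cases (12) and fell in 4 (4), with NQO1 (0.38) and CBR1 (0.42) among the risen (adjusted p = 0.059). That list was called without low glucose library 1 (0.03) or 2 (0.047) and without high glucose library 2 (0.047) or 3 (0.028). Fatty acid synthesis and desaturation genes rose in 8 of 27 cases (8), among them the elongase ELOVL6 (0.42), and fell in 1 (1), FADS3 (-0.16). Of these, 5 rose without low glucose library 1 (and 3 fell) or high glucose library 1, 4 without low or high glucose library 2, and 3 without low glucose library 3. Lipid droplet genes rose in 8 of 23 cases (9) and fell in 1 (3), LPIN2 (-0.23). The risen were 5 without low glucose library 2, 3 without low glucose library 3 and 4 without high glucose library 2, and 2 fell without low glucose library 1 or high glucose library 3. Iron homeostasis genes rose in 7 of 26 cases (7) and fell in 4 (5), the zinc and iron importer SLC39A14 (-0.65) among them. Fatty acid oxidation genes rose in 4 of 29 cases (4), ANGPTL4 (0.92, or 1.61 with limma voom and 1.43 with a pseudocount of 0.1) the most, and fell in 2 (2), or 1 without low glucose library 1 or high glucose library 2. Nuclear genes of oxidative phosphorylation rose in 7 of 70 cases (5) and fell in 1 (1), NDUFV1 (-0.12, or -0.18 after the GC and length correction). There 4 rose without low glucose library 1, 3 fell without high glucose library 1, and 2 fell without low glucose library 2 or high glucose library 3.

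Aryl hydrocarbon receptor targets rose in 4 of 12 cases (4) and fell in 4 (4) in high against low glucose, and p53 targets rose in 2 of 26 cases (3) and fell in 8 (8), SESN2 (-1.06) and GADD45A (-0.71) among them. Only 1 p53 target rose without low glucose library 1, 2 or 3 or high glucose library 2 or 3. NF-kB inflammation genes rose in 3 of 27 cases (4) and fell in 4 (6), with PTX3 (-1.54) and CXCL2 (-0.91) the largest. Interferon response genes rose in 6 of 32 cases (8) and fell in 2 (2), with IFIT1 at 0.65. In that list 3 rose without low glucose library 1, none fell without low glucose library 2 or 3 or high glucose library 1, and 1 fell without low glucose library 1 or high glucose library 2 or 3. Extracellular matrix genes rose in 9 of 38 cases (10) and fell in 10 (11), with COL1A1, a chain of collagen I, at 0.47. Immediate early genes rose in 7 of 26 cases (8) and fell in 6 (8), MYC (-0.72) and DUSP1 (-0.72) among the latter. Apoptosis genes rose in 9 of 27 cases (11), among them APAF1 (0.50), and fell in 4 (5). Autophagy and lysosome genes rose in 5 of 36 cases (5) and fell in 4 (4), NPC1 (-0.40) among them. Of 9 metallothionein and zinc genes none fell (1 without low glucose library 3) and 1 rose (0), MTF1 (0.23), at an adjusted p that median-of-ratios scaling took to 0.071. The MTF1 call was lost without low glucose library 1 (0.15) or 2 (0.08), high glucose library 2 (0.13) or 3 (0.13), or chrysin library 1, 2 or 3 (0.062, 0.062 and 0.064), with no filter (0.078) or with only the groups compared (0.10).

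Marker lists of cell types were measured as well in high against low glucose. Cardiomyocyte markers, with 8 of 34 tested, fell in 3 cases (3): the calcium pump ATP2A2 (-0.42), the natriuretic peptide NPPB (-0.52) and the connexin GJA1 (-0.26). That list was called without high glucose library 1 (0.044) and with a mean of at least 5 FPKM (0.018). Fibroblast markers rose in 4 of 19 cases (5) and fell in 4 (4), with COL1A1 and DDR2 (-0.47) on opposite sides. Smooth muscle markers rose in 1 of 13 cases (1), SMTN (0.37), and fell in 3 (3), MYLK (-0.24), CNN1 (-0.17) and TAGLN (-0.16). The CNN1 call was lost without low glucose library 1 (0.066) or high glucose library 2 (0.059), and the TAGLN call without low glucose library 2 (0.05) or high glucose library 2 (0.053); without the last, 2 rose. Endothelial markers rose in 2 of 8 cases (2), ENG (0.18) and SOX18 (0.69), both lost with the GC and length correction (0.09, adjusted p = 0.11, and 0.62, adjusted p = 0.061). The ENG call was lost without low glucose library 3 (0.089) or high glucose library 1 (0.067) or 2 (0.083), with no filter (0.064) or with only the groups compared (0.066). The SOX18 call was lost without low glucose library 1 (0.15) or 3 (0.14), high glucose library 1 (0.12) or 2 (0.14), or chrysin library 1, 2 or 3 (0.06, 0.062 and 0.061). It was also lost with median-of-ratios scaling (0.055), a pseudocount of 0.1 (1.11, adjusted p = 0.054), no filter (0.10) or only the groups compared (0.087), and stood at 1.30 (adjusted p = 0.0071) with limma voom. Leukocyte markers rose in 1 of 5 cases (1), CD14 (0.70), and epithelial markers in 1 of 8 cases (1), KRT18 (0.18). The median and the test differed in sign for the aryl hydrocarbon receptor, p53, NF-kB and immediate early lists (median above 0, test downward) and the epithelial list (median below 0, test upward). For drivers of ferroptosis the mean (-0.02) lay below 0 and the median and test above it.

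Of 16996 genes tested, 4002 changed between high and low glucose (limma, adjusted p under 0.05), with 2488 rising and 1514 falling. The groups did not overlap at 37.9% of the genes tested, where chance gives 10%. Changes were small, with a median size of 0.269 on the log2 scale among the called genes, and 93 genes changed at least 2-fold (23 up, 70 down). The share that rose was 62.2% with the values as deposited, 51.5% with median-of-ratios scaling and 51.2% with limma voom on recovered reads.

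High glucose with chrysin against high glucose asked what the flavonoid changed in cells kept in high glucose. Genes induced by hypoxia fell together. NDRG1, a stress-response gene induced by hypoxia (chromosome 8, 133237171 to 133302022, minus strand), fell 9.47-fold, from 110 ± 1.8 to 11.3 ± 1.9 FPKM (SD, n = 3; log2 -3.24, SE 0.09, adjusted p = 4.4e-09). CA9, a carbonic anhydrase and hypoxia marker, fell from 16 ± 1.6 to 1.98 ± 0.74 FPKM (-2.77, SE 0.17, adjusted p = 5.6e-07). TXNIP fell 4.76-fold, to 16.3 ± 0.86 FPKM (-2.25, SE 0.05, adjusted p = 1.2e-09), which was still above its low glucose level by 1.39. Extracellular matrix and inflammation genes fell as well, and replication histones rose. CA9 overlaps ARHGEF39 on the other strand.

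The other largest falls were STC1 (-2.23), MIR210HG (-2.07), the scavenger receptor COLEC12 (-2.37), RIPOR3 (-2.24) and TCP11L2 (-2.06). The largest rises included the histone H2BC5 (2.07), from 6.54 ± 0.62 to 29 ± 2 FPKM, the actin-bundling protein LCP1 (1.83), the coat protein SEC31B (1.73) and ANKRD1 (1.73), a cardiac stress and YAP target. RNA5-8SN1 (2.86) is a copy of the repeated 5.8S ribosomal RNA, FAM86HP (1.92) a pseudogene, and MIR4746 (1.91) and ZNF337-AS1 (1.82) overlap genes on the other strand, so reads of these 4 could belong to other copies or genes. ARRDC4 stood at -0.49 (adjusted p = 0.036), a call lost without high glucose library 1 (0.099) or 3 (0.093) and without chrysin library 2 (0.11) or 3 (0.088), and with a pseudocount of 0.1 (0.053) or no filter (0.056), while limma voom gave -0.81 (adjusted p = 0.0011).

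Of the 36 gene lists, 12 were called with chrysin against high glucose under both the preset and the estimated correlation. Genes induced by hypoxia fell in 25 of 29 cases (26 adjusted over the list alone), with a median of -0.89 (camera adjusted p = 2.1e-16, estimated 0.016). BNIP3 (-1.69), of mitophagy, and DDIT4 (-1.81), an inhibitor of mTORC1, fell. ADM (0.12) rose, a call lost without high glucose library 2 (0.081) or chrysin library 2 (0.068) or 3 (0.082) or with median-of-ratios scaling (0.065). Glycolysis genes fell in 22 of 25 cases (22 over the list alone, median -0.32, 2e-11, estimated 0.026), including the glucose transporter SLC2A1 (-0.93), ALDOC (-1.15) and PDK1 (-1.38), while PFKM (0.21) rose. MondoA targets fell in 13 of 20 cases (14 over the list alone, median -0.25, 0.00018, estimated 0.026) and rose in 2 (3 over the list alone), or in 1 without low glucose library 1, 2 or 3, high glucose library 2 or chrysin library 1 or 3. ATF4 targets fell in 24 of 35 cases (25 over the list alone, median -0.33, 1.3e-08, estimated 0.016), including the amino acid transporter SLC7A5 (-0.85) and XPOT (-0.70), and SLC7A11 alone rose over all genes tested, joined by another without low glucose library 1 or chrysin library 2. Aryl hydrocarbon receptor targets fell in 8 of 12 cases (10 over the list alone, median -0.57, 3.2e-06, estimated 0.016), CYP1B1 and SERPINB2 (-1.58) among them, and EDN1 (0.97) rose. That list shares SLC7A5 with the ATF4 targets and STC2 with the hypoxia genes, so these calls are not fully separate. Heat shock genes rose in 13 of 20 cases (15 over the list alone, median 0.23, 9.4e-05, estimated 0.019), including HSPA1B (0.49) and CHORDC1 (0.54), and HSPB1 (-0.40) fell. ADM, PFKM and HSPB1 were chosen after their values were seen.

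Extracellular matrix genes fell in 28 of 38 cases with chrysin against high glucose (30 over the list alone, median -0.32, camera adjusted p = 2.2e-11, estimated 0.016). COL1A2 (-0.76), a chain of collagen I, the proteoglycan LUM (-1.44) and the protease MMP2 (-1.54) fell, and COL4A1 (0.63), COL4A2 (0.21) and MMP3 (0.44) rose, the last not without high glucose library 2 (0.058) or chrysin library 2 (0.062). NF-kB inflammation genes fell in 17 of 27 cases and none rose (20 and 0 over the list alone, median -0.41, 1e-06, estimated 0.023), with the cytokines IL6 (-1.72), IL1B (-1.96) and CXCL8 (-1.19) as examples. Interferon response genes fell in 23 of 32 cases (25 over the list alone, median -0.53, 9.4e-08, estimated 0.016), including IFI44 (-1.11) and IFIT3 (-0.89), and rose in 2, IFI27 (2.05) and OAS3 (0.20). Fibroblast markers fell in 12 of 19 cases (12 over the list alone, median -0.45, 7.2e-05, estimated 0.019), including DCN (-1.75) and FAP (-1.46), and NT5E (0.61) rose. G2/M genes fell in 19 of 32 cases (19 over the list alone, median -0.13, 0.00013, estimated 0.034), including CCNB2 (-0.54) and TOP2A (-0.41), and rose in 2, BIRC5 (0.28) and BUB1 (0.11), the latter lost without chrysin library 1 (0.054) or 3 (0.058) and with median-of-ratios scaling (0.057). Replication histones rose in 11 of 18 cases and none fell (11 and 0 over the list alone, median 0.72, 0.00031, estimated 0.026), with H2AC6 at 1.43. The messages of these histones mostly lack a polyA tail, and RNA5-8SN1, which has none, also rose. Of 210 genes named as small RNAs without a tail, many of them pseudogene copies, 18 rose and 6 fell (median 16 reads over all libraries). COL4A1, COL4A2, MMP3, IFI27, OAS3 and BUB1 were chosen after their values were seen.

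In 4 lists the call with chrysin against high glucose was lost with an estimated correlation. Mitochondrially encoded genes rose in 12 of 13 cases (13 over the list alone, median 0.42; adjusted p = 2.1e-07, and adjusted p = 0.082 with an estimated correlation), with MT-CO1 (0.42) and MT-ND5 (0.54) as examples. S phase genes fell in 16 of 40 cases and rose in 10 (16 and 10 over the list alone; adjusted p = 0.038, and adjusted p = 0.13 with an estimated correlation), with RRM2 (-0.72) and MCM4 (-0.44) among those that fell. That call was lost without high glucose library 1 (0.11), and 6, 6 and 4 rose without chrysin library 1, 2 and 3. Immediate early genes fell in 15 of 26 cases and rose in 6 (15 and 6 over the list alone; adjusted p = 0.01, and adjusted p = 0.23 with an estimated correlation), with EGR1 (-1.91) and DUSP1 (1.03) on opposite sides. With a mean of at least 5 FPKM the immediate early (0.086) and S phase (0.094) calls were lost. Smooth muscle markers rose in 7 of 13 cases and fell in 2, DES (-0.71) and MYOCD (-0.90), with 7 and 2 over the list alone (adjusted p = 0.038, and adjusted p = 0.16 with an estimated correlation). The actins ACTA2 (1.72) and ACTG2 (1.28) and the actin-binding protein TAGLN (0.72) were among those that rose.

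The remaining 20 lists were not called with chrysin against high glucose (camera adjusted p from 0.093 to 0.99), and counts adjusted over the list alone stand in brackets. ER unfolded protein genes, so much lower in high than in low glucose, rose in 10 of 27 cases (12) and fell in 8 (9), with DNAJB11 (0.46) and HERPUD1 (-0.88) on opposite sides. Drivers of ferroptosis rose in 11 of 26 cases (11) and fell in 9 (10), with CYB5R1 (0.58) and DPP4 (-0.77) as examples. Suppressors of ferroptosis rose in 9 of 32 cases (9) and fell in 15 (15), with TXNRD1 (0.42) and CD44 (-0.32) as examples. Iron homeostasis genes rose in 9 of 26 cases (9) and fell in 7 (7), with the ferritin light chain FTL at -0.43. Glutathione and NRF2 targets rose in 9 of 30 cases (10) and fell in 10 (11), with SLC6A9, a glycine transporter, at -1.35. Fatty acid synthesis and desaturation genes rose in 9 of 27 cases (10) and fell in 9 (11), with the desaturase FADS1 (-0.54) and PNPLA3 (-0.68) beside SCD. Cholesterol synthesis genes rose in 6 of 27 cases (6) and fell in 10 (11), with INSIG1 (-0.83) and TMEM97 (0.62) as examples. Fatty acid oxidation genes rose in 9 of 29 cases (10), UCP3 (1.08) and HADH (0.40) among them, and fell in 6 (7). Lipid droplet genes rose in 6 of 23 cases (7) and fell in 6 (7), with the lipase PNPLA2 at -0.77, and 3 rose without high glucose library 2. Nuclear genes of oxidative phosphorylation rose in 17 of 70 cases (16) and fell in 10 (9), with ATP5PD at 0.38. Only 4 of these fell without high glucose library 1 or chrysin library 3, and 5 without chrysin library 2.

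Targets of TGF-beta and YAP rose in 11 of 29 cases (11) with chrysin against high glucose and fell in 8 (9), with ID3 at 1.16. Of 26 p53 targets 4 rose (4) and 9 fell (9), with AEN at 0.49. Apoptosis genes rose in 8 of 27 cases (8) and fell in 11 (11), including BMF (-2.04) and BBC3 (-1.37), which promote cell death. Autophagy and lysosome genes rose in 9 of 36 cases (9), NPC1 (0.61) among them, and fell in 13 (13), ULK1 (-0.95) among them. Metallothionein and zinc genes rose in 4 of 9 cases (4) and fell in 3 (3), with MT2A at -1.72. Ribosomal protein genes rose in 14 of 76 cases (12) and fell in 5 (5), but without high glucose library 1 as many as 37 rose and the list was called (adjusted p = 0.00015). Cardiomyocyte markers rose in 1 of 8 cases (1), the cardiac actin ACTC1, from 0.389 ± 0.058 to 4.83 ± 0.58 FPKM (SD, n = 3; log2 2.58, adjusted p = 7.7e-07), and fell in 3 (3), GJA1 (-0.72), DES (-0.71) and NPPB (-0.37). Endothelial markers rose in 1 of 8 cases (1), ESAM (0.94), and fell in 5 (5), ROBO4 (-1.20) the most, but in 3 without high glucose library 1 or 2 or chrysin library 1. SOX18 (-0.67) was not called there (0.093, 0.10 and 0.083) or without chrysin library 2 (0.078), nor with no filter (0.066). TEK (-0.45) was not called without low glucose library 1, 2 or 3 (0.054, 0.056 and 0.06), high glucose library 1, 2 or 3 (0.11, 0.10 and 0.059), or chrysin library 1 or 3 (0.12 and 0.13), nor with no filter (0.092) or only the groups compared (0.062). Leukocyte markers fell in 2 of 5 cases (2), CD14 (-0.85) and LAPTM5 (-0.64), and 1 rose without high glucose library 2 or chrysin library 1. The LAPTM5 call was lost without high glucose library 2 (0.12) or 3 (0.06) and without chrysin library 1 (0.068) or 2 (0.11), with no filter (0.091) and with only the groups compared (0.067). Epithelial markers rose in 1 of 8 cases (1), KRT7 (0.42), and fell in 3 (3), KRT18 (-0.58), KRT8 (-0.39) and CLDN7 (-0.56). The KRT7 call was lost without high glucose library 2 (0.26, adjusted p = 0.074) or chrysin library 2 (0.084) or with no filter (0.066). The CLDN7 call was lost without low glucose library 1, 2 or 3 (0.058, 0.055 and 0.052), high glucose library 2 (0.16) or chrysin library 2 or 3 (0.10 and 0.12), with no filter (0.088) or with only the groups compared (0.071). With limma voom ESAM stood at 2.55, SOX18 at -1.17, TEK at -0.79 and CLDN7 at -1.06, and with a pseudocount of 0.1 ESAM at 1.84, SOX18 at -1.02 and CLDN7 at -0.89; a pseudocount of 1 put ESAM at 0.60. The median of the glutathione and NRF2 list lay above 0 and its test pointed down, and the means of the iron (0.03) and cardiomyocyte (0.12) lists lay above 0 with median and test below it.

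**Figure D2:**
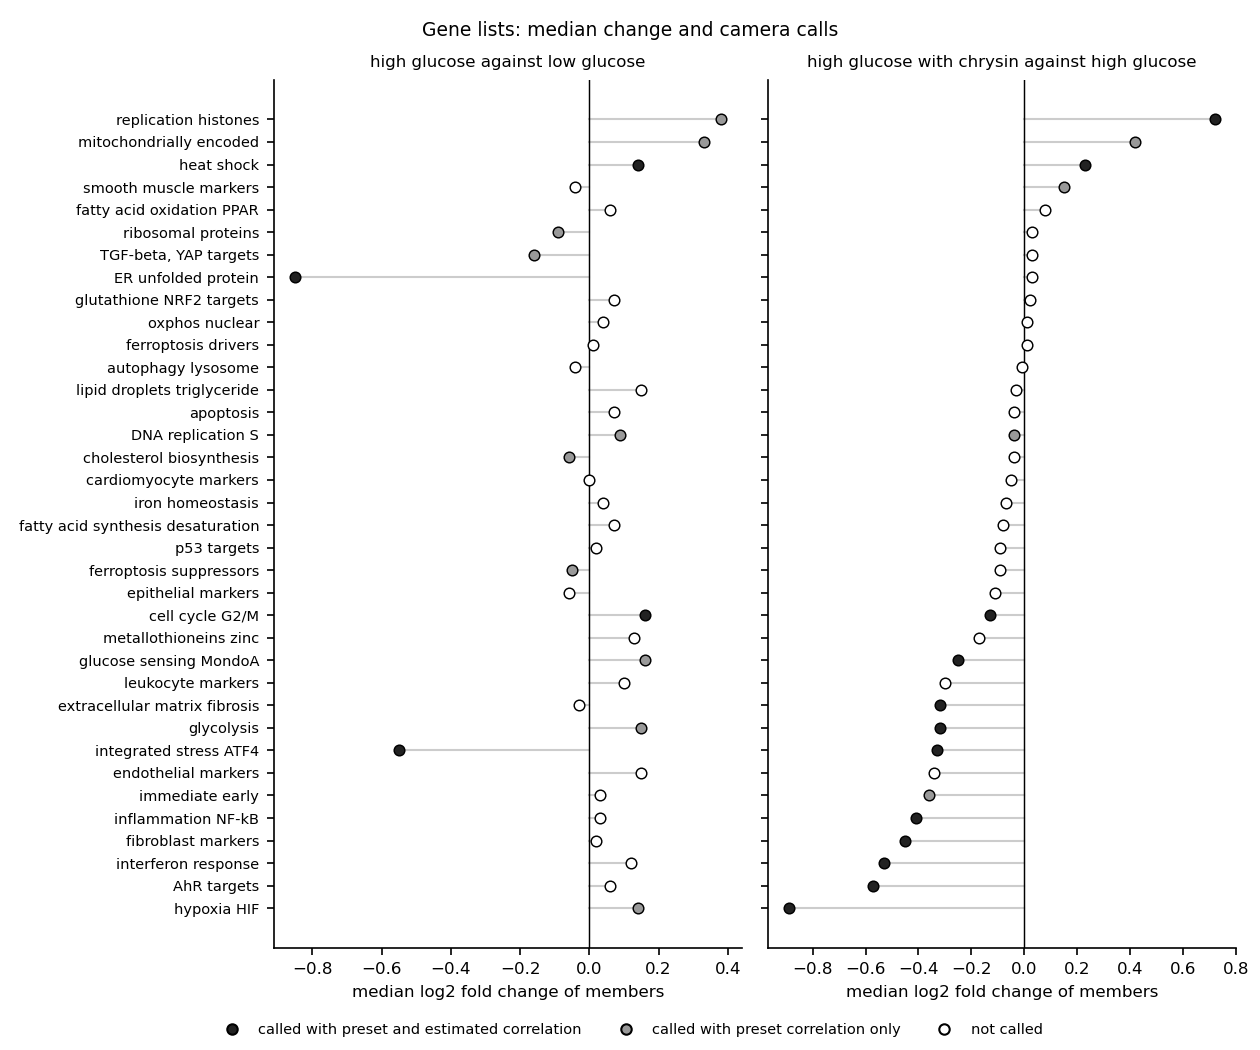
Median log2 fold change of each of the 36 gene lists in high against low glucose (left) and in high glucose with chrysin against high glucose (right). Point shading gives whether camera called the list with both correlations, with the preset correlation only, or not; the ER unfolded protein list lies at -0.85 on the left and the hypoxia list at -0.89 on the right.

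With chrysin 7792 of 16996 genes changed against high glucose (limma, adjusted p under 0.05), with 4234 rising and 3558 falling. This split is for the values as deposited, where the median log2 fold change over all genes tested was 0.03, and may depend on scaling. The groups did not overlap at 54.3% of the genes, where chance gives 10%. The median size of a called change was 0.37 on the log2 scale, and 551 genes changed at least 2-fold (363 up, 188 down). Among 2569 long noncoding genes 589 rose and 146 fell, against 3350 and 3298 of 12587 protein-coding genes.

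High glucose with chrysin against low glucose asked how far cells with both treatments stood from low glucose cells. DDIT3 was 19.6-fold lower than in low glucose, at 4.82 ± 0.47 against 103 ± 5.2 FPKM (SD, n = 3; log2 -4.29, SE 0.07, adjusted p = 2.4e-11). NDRG1 was 6.09-fold lower (-2.61, SE 0.09, adjusted p = 9.6e-09) and H2BC5 6.44-fold higher (2.69, SE 0.08, adjusted p = 2.3e-09). SLC7A11 was higher (0.55), as were TFRC (0.61) and HMOX1 (0.74), and GPX4 was lower (-0.34).

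Among the gene lists 16 were called with chrysin against low glucose, and 10 of them also with an estimated correlation. Counts adjusted over the list alone stand in brackets, each count of fallen or risen genes before it being over all genes tested. ATF4 targets fell in 31 of 35 cases (31; median -1.06, estimated adjusted p = 0.0061), ER unfolded protein genes in 22 of 27 (22; -0.63, 0.014), hypoxia genes in 22 of 29 (22; -0.60, 0.014) and extracellular matrix genes in 31 of 38 (31; -0.34, 0.014). Aryl hydrocarbon receptor targets fell in 7 of 12 cases (8; -0.61, 0.02), NF-kB inflammation genes in 16 of 27 (16; -0.34, 0.025), interferon response genes in 17 of 32 (19; -0.43, 0.021) and fibroblast markers in 14 of 19 (14; -0.46, 0.017). Heat shock genes rose in 16 of 20 cases (16; 0.42, 0.014) and replication histones in 15 of 18 (15; 1.06, 0.017). In each of these 10 lists 0 to 3 members passed the test the other way.

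The other 6 calls with chrysin against low glucose were lost with an estimated correlation. Mitochondrially encoded genes rose in 13 of 13 cases (13 over the list alone; adjusted p = 1.5e-08, and adjusted p = 0.07 with an estimated correlation). Glycolysis genes fell in 16 of 25 cases and rose in 3 (16 and 3; adjusted p = 4.4e-05, and adjusted p = 0.13 with an estimated correlation). Cholesterol synthesis genes fell in 15 of 27 cases and rose in 5 (15 and 5; adjusted p = 0.0036, and adjusted p = 0.22 with an estimated correlation). Suppressors of ferroptosis fell in 15 of 32 cases and rose in 7 (15 and 7; adjusted p = 0.035, and adjusted p = 0.095 with an estimated correlation). Ribosomal protein genes fell in 20 of 76 cases and rose in 4 (16 and 3; adjusted p = 0.0051, and adjusted p = 0.7 with an estimated correlation), with 33 fallen and 8 risen without high glucose library 1 and 13 and 2 without chrysin library 1. Only 2 rose without low glucose library 2, and 1 without low glucose library 3 or chrysin library 3. Immediate early genes fell in 11 of 26 cases and rose in 6 (11 and 7; adjusted p = 0.048, and adjusted p = 0.35 with an estimated correlation). That call was lost without low glucose library 2 (0.065) or high glucose library 1 (0.058) or 2 (0.054), with median-of-ratios scaling (0.059) and with the GC and length correction (0.057). The p53 targets fell in 14 of 26 cases and rose in 8 without a call (14 and 9; adjusted p = 0.051), with 5 risen without low glucose library 2 or chrysin library 2. They were called without low glucose library 1 (0.044) or 3 (0.049), high glucose library 3 (0.047) or chrysin library 1 (0.04) or 2 (0.031). With a mean of at least 5 FPKM the immediate early (0.17) and suppressor (0.11) calls were lost and the p53 (0.016) and cardiomyocyte (0.021) lists were called. The other 19 lists had adjusted p from 0.086 to 0.83. The median lay above 0 with the test pointing down for the metallothionein and fatty acid synthesis lists. Means differed in sign from the test for the iron (0.06), cardiomyocyte (0.02), metallothionein (0.03), fatty acid synthesis (0.01), apoptosis (-0.02) and ferroptosis driver (-0.01) lists.

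In all, 8664 of 16996 genes differed between high glucose with chrysin and low glucose (limma, adjusted p under 0.05), with 5048 higher and 3616 lower. The median log2 fold change over all genes tested was 0.051, against 0.025 for high against low glucose, whose split moved with scaling. The split given here is for the values as deposited and may depend on scaling too. The groups did not overlap at 60% of the genes, where chance gives 10%, and 725 genes differed at least 2-fold (451 up, 274 down).

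**Figure D3:**
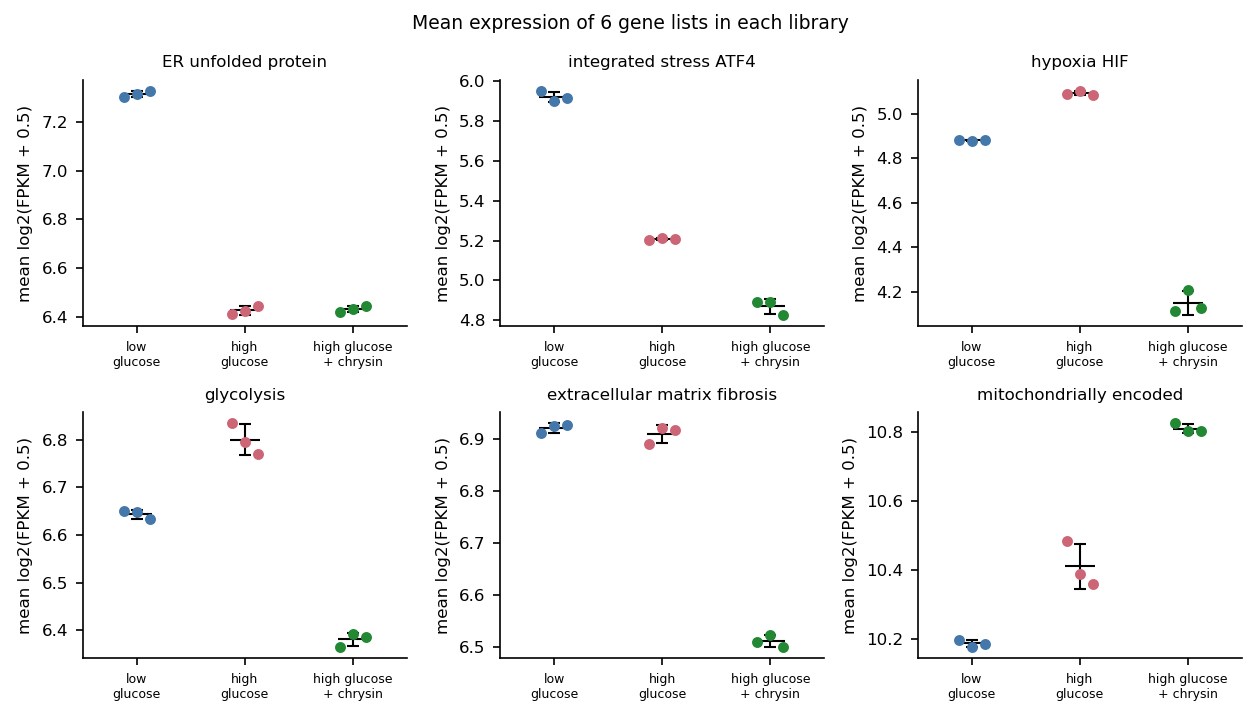
Mean log2(FPKM + 0.5) over the tested genes of 6 lists in each library; points are libraries, horizontal bars are group means and error bars are the SD (n = 3), and the vertical axes do not start at 0. The ER unfolded protein list had group means of 7.31 in low glucose and 6.43 in both high glucose groups, and the hypoxia list 4.88, 5.09 and 4.15.

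The last comparison asked which genes changed with high glucose and then in the opposite direction with chrysin, here called changed back. No group had chrysin in low glucose. An effect of chrysin that does not depend on glucose therefore cannot be told from a reversal of the glucose effect. ANKRD1 fell with high glucose (-1.21) and rose with chrysin (1.73), as did RGS4 (-0.70 and 1.21), a regulator of G protein signalling, the phosphate transporter SLC20A2 (-0.59 and 0.74), CD274 (-1.02 and 1.11), the immune checkpoint ligand PD-L1, and SH3RF2 (-0.73 and 1.66). TXNIP, KIF20A (0.47 and -0.79) and LDHA (0.32 and -0.87) rose and then fell. CD274 was at 12.8 ± 0.57 FPKM in low glucose, 6.07 ± 0.28 in high glucose and 13.7 ± 0.69 with chrysin (SD, n = 3), and did not pass the test between the last and low glucose (0.09, adjusted p = 0.25).

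Of the 4002 genes changed by high glucose, 1454 (36.3%) changed back with chrysin: 902 rose and then fell, and 552 fell and then rose. Another 1032 changed further the same way. Of the 1454 genes, 777 did not differ from low glucose by the test, 520 were past the low glucose level on the other side, and 157 were still on the high glucose side. Independent lists of these sizes would share 898 genes in opposite directions (520.8 and 377.2) and 936.8 in the same direction. The high glucose libraries enter both comparisons with opposite sign, and 100 simulations of unchanged groups against them gave a median of 0 and at most 1 gene changed back. No gene truly changed in these simulations, so an overlap near 0 was set in advance, and at most 0 genes changed the same way. They do not show how many opposite calls the shared libraries add when many genes change. Across genes, which are not independent replicates, the fold changes of both comparisons had a correlation of -0.197, against -0.5 (-0.527 to -0.468) in the simulations, and a covariance of -0.02495 against -0.0142 (-0.016 to -0.013). Part of the excess over independent lists may come from the shared libraries, which 3 libraries do not allow to be split.

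**Figure D4:**
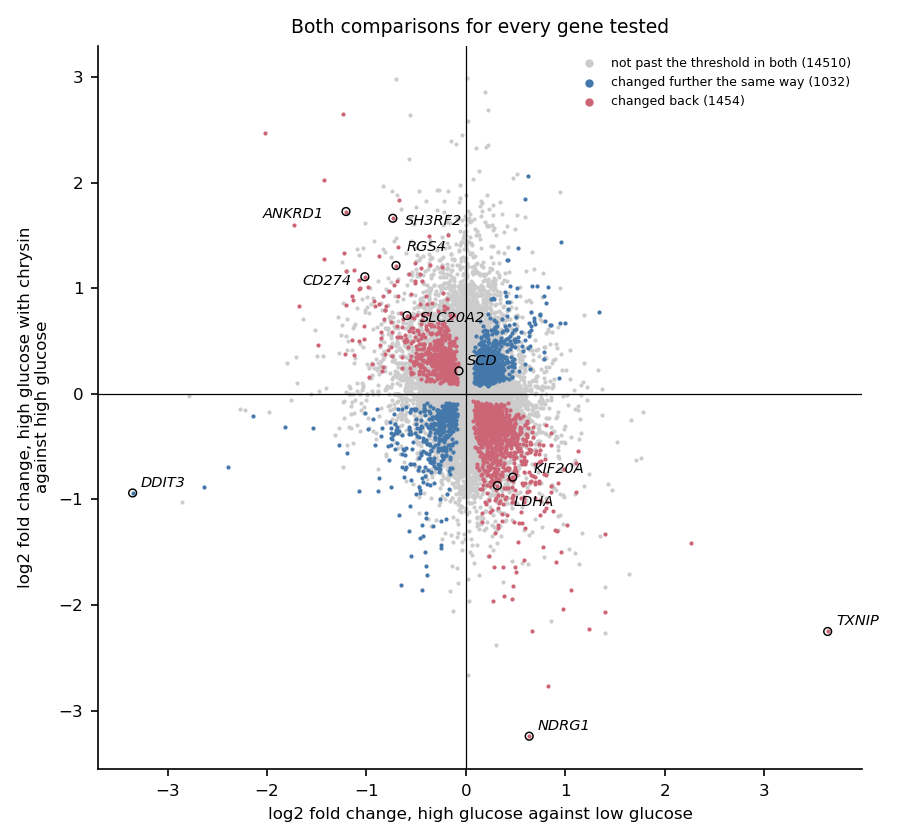
Log2 fold change of each of the 16996 genes tested in high against low glucose (horizontal) and in high glucose with chrysin against high glucose (vertical). Red points are the 1454 genes that changed back, blue points the 1032 that changed further the same way, and grey points the rest; circles mark named genes such as TXNIP at 3.64 and -2.25.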

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

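The GC and length correction, leaving out mitochondrial genes, and the list counts without single libraries were chosen after the results were seen. Requiring an absolute log2 fold change of at least 1 left 93 genes in high against low glucose, 551 with chrysin against high glucose, 725 with chrysin against low glucose and 19 changed back, fewer by construction. With an estimated correlation camera called 4 lists in high against low glucose and 10 with chrysin against low glucose, and fry, which does not compare a list with other genes, called 26, 29 and 30. SCD with chrysin against low glucose was 0.09 (adjusted p = 0.058) with median-of-ratios scaling, and SCD in high against low glucose was -0.10 (adjusted p = 0.018) with limma voom; over all alternatives its adjusted p ran from 0.002 to 0.058 and from 0.018 to 0.43. The cause was not tested. Leaving out 1 library at a time gave 2971 to 3811 genes in high against low glucose, 6812 to 7660 with chrysin against high glucose, 7707 to 8938 with chrysin against low glucose and 1088 to 1392 changed back. It called 14 to 15, 16, and 15 to 17 lists, and SCD ranged from -0.10 to -0.04, 0.19 to 0.24 and 0.12 to 0.16. Under the other settings high against low glucose gave 3097 (no filter) to 4509 (limma voom) genes. Among 6145 pairs of a named result and a setting, 124 calls were lost, 8 were gained and 0 reversed, in 26 of 326 named results.

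With the replicate number as a block, 3693, 7546 and 8423 genes were called, 1321 changed back, and 14, 16 and 15 lists were called. Deviations of same-numbered libraries had correlations of -0.015 to 0.008, so the libraries share only a number. TMM scaling with edgeR, DESeq2 and a filter on CPM, which were planned for deposited counts, were not run. At 18171842 to 23024300 reads a simulated change of 0.25 was called in 18% of genes for high against low glucose. For chrysin against high glucose it was called in 30%. The simulations changed far fewer genes than the 4002 and 7792 called in the data, so their adjusted threshold was stricter. These shares cannot be carried over to the data, and how completely small changes are listed was not measured.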

Other observations

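The tests of polyA selection, of library scaling and of a return to the low glucose level were chosen after the results they measure were seen, and the GC and length correction was added after the data were seen. The split of small RNAs at 100 reads, and leaving NFAT5 itself out of its targets with an SE between genes, were also set after the values were seen.

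Noncoding genes that changed with chrysin against high glucose mostly rose. A smaller share of them than of coding genes was called in each direction, so the shares do not compare the size of the shift. Among 1070 pseudogenes 189 rose (17.7%) and 73 fell (6.82%), among long noncoding genes 22.9% rose and 5.68% fell, and among coding genes 26.6% rose and 26.2% fell. The median log2 fold change over all genes tested was 0.19 for long noncoding genes, 0.09 for pseudogenes and 0 for coding genes. In high against low glucose, too, long noncoding genes were called less often (4.01% rose, 4.24% fell) than coding genes (18.5% and 10.5%). No test compared the classes. At an equal 18171842 reads 24636 ± 140 genes were detected with chrysin, against 23366 ± 55 in high glucose and 23286 ± 69 in low glucose (SD, n = 3). Small RNAs with over 100 reads stood on both sides of 0, among them SNORA71B at 0.68, SNORD17 at -0.07 and SNORA73B at -0.52. Known targets of the osmotic stress factor NFAT5 also moved both ways in high against low glucose, with SLC6A6 (0.44) and AKR1B1 (0.22) higher and SLC38A2 (-0.26) lower. These small RNAs were chosen after their values were seen.

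For the noncoding genes that rose with chrysin, depth was tested by genes detected. At equal reads the lowest chrysin library detected 1048 more genes than the highest high glucose library, so depth is excluded for the number detected. That count covers genes of all classes, and the noncoding fold changes were not recomputed at equal reads. Genomic DNA is excluded as the main source of the gain of the called noncoding genes, a median of 1.05 FPKM. The 580 genes of families taken as silent in these cells, 97 of them with a read, gained 0.13% of that. These called genes were picked for their change, and genomic DNA was not tested for the number of genes detected. Less complete polyA selection cannot be told apart: 210 genes named as small RNAs without a polyA tail had a median of 0.25 (SE 0.061), against 0.19 for long noncoding genes. Of these 18 rose and 6 fell, and the 10 with over 100 reads had a median of 0.01 (SE 0.17). Many of the 210 carry names of pseudogene copies, such as RNU6-920P, and their median was 16 reads over all libraries. The set is therefore a weak measure of polyA selection. Unspliced RNA cannot be told apart either. The odds ratio of overlapping the body of a coding gene, on either strand, was 0.964 (0.818 to 1.14, Fisher's exact p = 0.68). Overlap on the other strand counts in it, so it is a loose measure of unspliced RNA. An effect of chrysin on these transcripts is untested and stays open.

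The 50 tested genes of the hypoxia and glycolysis lists fell with chrysin by a median log2 of -0.49 (SE 0.12). GC content and length are excluded as the whole cause, with -0.48 after their correction. After median-of-ratios scaling the median was -0.51. The scaling factors were 0.9979 to 1.0014 in high glucose and 1.0167 to 1.0222 with chrysin, too close together to remove the fall. The choice of that scaling is therefore not the cause, but neither scaling could show a change in total RNA. A return to the low glucose level is excluded for the hypoxia genes, whose median against low glucose was -0.60 (SE 0.18). For the glycolysis genes that median, -0.14 (SE 0.10), did not decide it. By library the mean log2 of the glycolysis list was 6.38 (SD 0.01) with chrysin and 6.64 (SD 0.01) in low glucose (n = 3). Of its 25 genes 16 were lower and 3 higher, which together argues against a mere return for the list as a whole. A candidate explanation that stays open is lower activity of hypoxia-inducible factor with chrysin, for which no protein was measured.

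The 62 tested genes of the ER unfolded protein and ATF4 lists were lower in high than in low glucose by a median of -0.56. GC content and length are excluded as the whole cause, with -0.60 (SE 0.11) after their correction. Hyperosmotic stress by glucose needed NFAT5 targets to rise by at least 0.3, and it cannot be told apart, since 6 targets went both ways with a mean of 0.13 (SE between genes 0.12). Glucose shortage in the low glucose cells may account for the pattern and was not tested, since no group had another sugar level.

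The splits of 6 libraries into 3 and 3 number 10, too few for a share under 0.05. In each comparison 1 split, the real one, gave as many genes: 4002, 7792 and 8664, with 1 gene as the highest of the other splits.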
